A study of Rattus norvegicus with 6 samples.

How the data were processed

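For each probe set, 6 values were analysed, from 3 control samples and 3 samples given 10 nM GnRH, all from rat pituitary organ culture. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on a column and turned into biotin-labelled cRNA, which was hybridised to 1-colour arrays. The deposited values are array intensities on a linear scale, produced with RMA per the submitters' processing notes; the software, its version and any filter are not given in the sources used here. RMA (robust multi-array average) usually removes background, makes the distribution of values equal across arrays and combines the probes of a probe set into 1 value, and is usually reported as log2; the values here are not on a log scale. The quartiles of the 6 arrays were close but not identical. The table held 31042 probe sets, 0 control probe sets of the manufacturer, 0 missing values and no detection calls, so no probe set could be called absent.

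Samples were grouped by their titles. Gene names came from the array annotation supplied with the series, updated through gene identifiers against the GRCr8 gene table, which was used for names and for the order of neighbouring genes alone. Of the probe sets, 20826 had 1 gene symbol, 436 had several and 9780 were not listed there; none was named from a probe set with several symbols or no listing. A current gene was matched by gene identifier for 20758 probe sets and by accession for 2, while 66 kept the symbol of the annotation. The named probe sets covered 14217 genes.

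The linear values were turned into log2 values with no pseudocount. GnRH and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a linear model per probe set whose variance estimate borrows from all probe sets), as a 2-sided moderated test with no covariate and no filter on dim probe sets. P-values were adjusted by Benjamini-Hochberg over all 31042 probe sets, and an adjusted p under 0.05 was the threshold. A log2 fold change is the mean of the 3 GnRH arrays minus the mean of the 3 control arrays. Gene lists were tested with camera from limma, which asks whether the genes of a list moved relative to all other genes, with its preset inter-gene correlation of 0.01, over 14217 genes with 1 probe set each (the one with the highest mean) and with Benjamini-Hochberg over 27 lists. For the members of each list, the count past the threshold over all probe sets is given beside the count adjusted over the list alone.

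Before the data were examined, 17 pathway lists and 10 lists of cell type markers were fixed from general knowledge, with 738 entries and 693 different genes, of which 614 were measured. The pathway lists were gonadotrope hormone and identity genes, immediate early transcription factors, MAP kinase and G protein feedback regulators, GnRH receptor signalling components, secretory granule and exocytosis genes, the activin, inhibin and BMP pathway, the unfolded protein response, neuropeptides and secreted growth factors, steroid and nuclear receptors, cytokine, chemokine and NF-kappaB genes, circadian clock genes, actin cytoskeleton and SRF target genes, glycolysis and hypoxia genes, cholesterol synthesis genes, heat shock and oxidative stress genes, cell cycle genes and, for comparison, ribosomal proteins. The marker lists were for somatotropes, lactotropes, corticotropes and melanotropes, thyrotropes, folliculostellate and stem-like cells, endothelium, macrophages and leukocytes, fibroblasts and pericytes, the posterior lobe and glia, and red blood cells. Some genes stand in several lists. The genes to be named were also set by rule: Lhb, Fshb, Cga, Gnrhr and Egr1 in any case; the 12 genes with the largest rise and up to 12 with the largest fall among those past the threshold whose groups did not overlap, each by its probe set with the smallest p-value; and up to 4 members of each list with the smallest p-values. Elsewhere a gene stands for its probe set with the highest mean.

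The test was tried on simulated data for all 31042 probe sets, each drawn independently with a variance from the distribution fitted to the real arrays. Of 50 simulated changes at each size, 33 were recovered at a log2 change of 0.58, 49 at 1.00, 50 at 1.50 and 50 at 2.00, and 10 of 192 calls were false. In a separate simulation of this kind with 1 list moved, camera called that list and 0 of the others. Its genes were independent, whereas the estimated correlation in the real arrays was 0.747 for ribosomal proteins. It therefore cannot show how often camera calls unmoved lists in the real arrays.

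Alternatives tried were centring each array on its median, repeating quantile normalization, cyclic loess, leaving out dim probe sets, an intensity trend or robust variances in eBayes, array weights, the replicate number as a block, each array left out in turn, other thresholds, other rules for genes with several probe sets, camera with an estimated correlation, and fry, another limma test of whether a list's genes move on balance in 1 direction. The range of each array's values as a covariate was added after the data were seen, as was the mean log2 level of the 4 Xist probe sets of each array.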

Results

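The pituitary is the gland below the brain that secretes growth hormone, prolactin, thyrotropin, corticotropin and the gonadotropins LH and FSH. GnRH (gonadotropin-releasing hormone) is the hypothalamic peptide that acts on gonadotropes, the pituitary cells that make LH and FSH. Transcript levels were measured on 1 array per sample in whole-organ cultures of rat pituitary, with 3 control samples and 3 samples given 10 nM GnRH. The comparison asked which transcripts differed between cultures with and without GnRH. The length of the treatment is not given in the sources used here. Each array gave an intensity for 31042 probe sets, with a median of 64.5 to 67.0 across the 6 arrays on the linear scale. The titles number the samples of each group 1 to 3, but the descriptions of the 3 GnRH samples all end in the number 1, and no label says that samples came from separate cultures or animals. The p-values therefore measure the spread between these samples, which may be technical.

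Control replicate 3 stood apart from the other controls. The log2 values of controls 1 and 2 had a Pearson correlation of 0.994 across probe sets, which are not independent replicates, whereas control 3 had 0.983 with control 1 and 0.986 with control 2. Its correlation with the GnRH arrays was higher, from 0.988 to 0.991, and GnRH arrays had 0.992 to 0.994 among themselves. On the first principal component, which took 48.0% of the variance, control 3 lay at 11.7, between the GnRH arrays at 7.82, 16.2 and 18.1, while controls 1 and 2 lay at -29.6 and -24.2. The second component, with 21.9% of the variance, separated control 3 at -26.7 from all other arrays. Sex-linked transcripts, looked up after the data were seen, followed the same division. Xist, the RNA that silences 1 X chromosome in female cells, had log2 values of 3.91 and 3.66 in controls 1 and 2, 9.77 in control 3 and 9.73, 9.16 and 9.49 with GnRH on the probe set with the largest difference. Its other 3 probe sets divided the arrays in the same way. Eif2s3y, a gene of the Y chromosome, had 6.48 and 6.56 in controls 1 and 2, 2.76 in control 3 and 2.42, 2.29 and 2.06 with GnRH. Of the other Y-linked genes, 1 probe set of Uty ran the opposite way (6.27 and 6.31, then 7.44, then 7.41, 7.47 and 7.52). Sry was slightly higher in controls 1 and 2 (5.13 and 5.06) than in control 3 (4.75) and with GnRH (4.99, 4.89 and 4.90). The other Uty probe set and Tspy1 overlapped across the division. The sex of the animals is not given in the sources used here. Low Xist thus went with 2 of 3 controls and 0 of 3 GnRH samples, and leaving out control 3 set arrays with low Xist against arrays with high Xist. An alternative chosen after the data were seen took the mean Xist level of each array as a covariate, in which control 3 was the 1 control at the Xist level of the GnRH arrays. Control 3 carried 0.942 of the weight of the controls in that estimate, against 0.049 and 0.0088 for controls 1 and 2. It therefore set the GnRH arrays against control 3 almost alone, with that lone array assumed to vary like the others, and does not show which calls are stable. The range of values, the other covariate added later, divided the arrays in much the same way. On the log2 scale it was 4.98 and 5.04 in controls 1 and 2, 5.25 in control 3 and 5.17, 5.19 and 5.27 with GnRH. The 2 covariates are thus not separate checks.

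**Figure D1:**
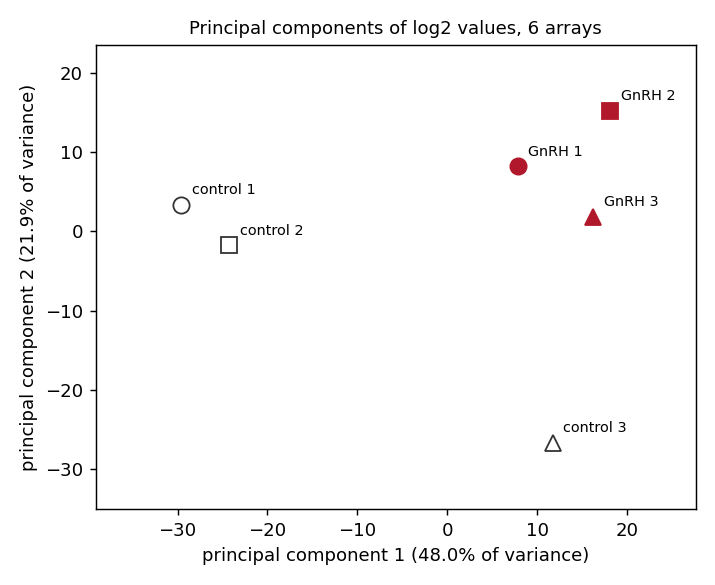
Position of the 6 arrays on the first (48.0% of variance) and second (21.9%) principal components of the log2 values, in component score units. Open symbols are controls and filled symbols GnRH samples; control 3 lies at 11.7 on the first component, on the side of the GnRH arrays, and at -26.7 on the second, below all others.

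GnRH-treated pituitaries had more mRNA for the GnRH receptor and for a set of genes led by Dmp1 and Creb3l1, and less for Inhba and Plau. Dmp1, which encodes an acidic secreted phosphoprotein known from bone and dentin, rose by 1.48 ± 0.12 (SE) on the log2 scale, or 2.79-fold (limma, Benjamini-Hochberg adjusted p = 0.00586). Creb3l1, a transcription factor held in the endoplasmic reticulum membrane until it is cut free, rose 2.46-fold, with an SE of 0.15 on the log2 scale (limma adjusted p = 0.00799). Inhba, the activin beta-A subunit, fell by 1.03 ± 0.18 (limma adjusted p = 0.0399), a call lost with each array centred on its median and with robust variances, and Plau, the urokinase-type plasminogen activator, fell by 0.85 ± 0.11 (limma adjusted p = 0.0144). In each of these genes the 3 GnRH arrays lay on the same side of all 3 controls.

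The other genes with the largest rises were Mark2 (1.27, a microtubule-regulating kinase), Prrt1 (1.14, a proline-rich membrane protein), Nfic (1.11, a nuclear factor I transcription factor), Nisch (1.06, nischarin), Syvn1 (1.05, the ubiquitin ligase of endoplasmic reticulum-associated degradation), Gnrhr (1.04 and 1.12 on its 2 probe sets) and Ptms (0.99, parathymosin), all as log2 fold changes. The depalmitoylating enzyme Abhd17a, the amyloid precursor-like protein Aplp1 and P3h4, a partner of collagen-modifying enzymes, each rose by 1.0. The SEs of all these genes ran from 0.10 to 0.21. Their limma adjusted p-values ran from 0.00586 for Prrt1 and Syvn1 to 0.0317 for Mark2. Only 8 different named genes fell. Besides Inhba and Plau these were Reg3a (-0.82, a secreted lectin), Lcn2 (-0.78, the iron-siderophore carrier lipocalin 2), Slc5a3 (-0.69, a myo-inositol transporter), Msmo1 (-0.61, a sterol-synthesis oxidase), Calcb (-0.55, beta-CGRP) and Timp3 (-0.50, a metalloproteinase inhibitor), with limma adjusted p-values from 0.0266 for Lcn2 to 0.0494 for Timp3. Several sizes depended on the probe set: with the mean of all probe sets of a gene, Prrt1 rose by 0.55, P3h4 by 0.60 and Inhba fell by 0.65, while Nfic (0.62, limma adjusted p = 0.0745), Timp3 (-0.27, 0.245) and Slc5a3 (-0.48, 0.111) did not pass. Among the probe sets past the threshold, the largest rise was in an unnamed one, at 2.26, and the largest fall in another unnamed one, at -1.12.

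**Figure D2:**
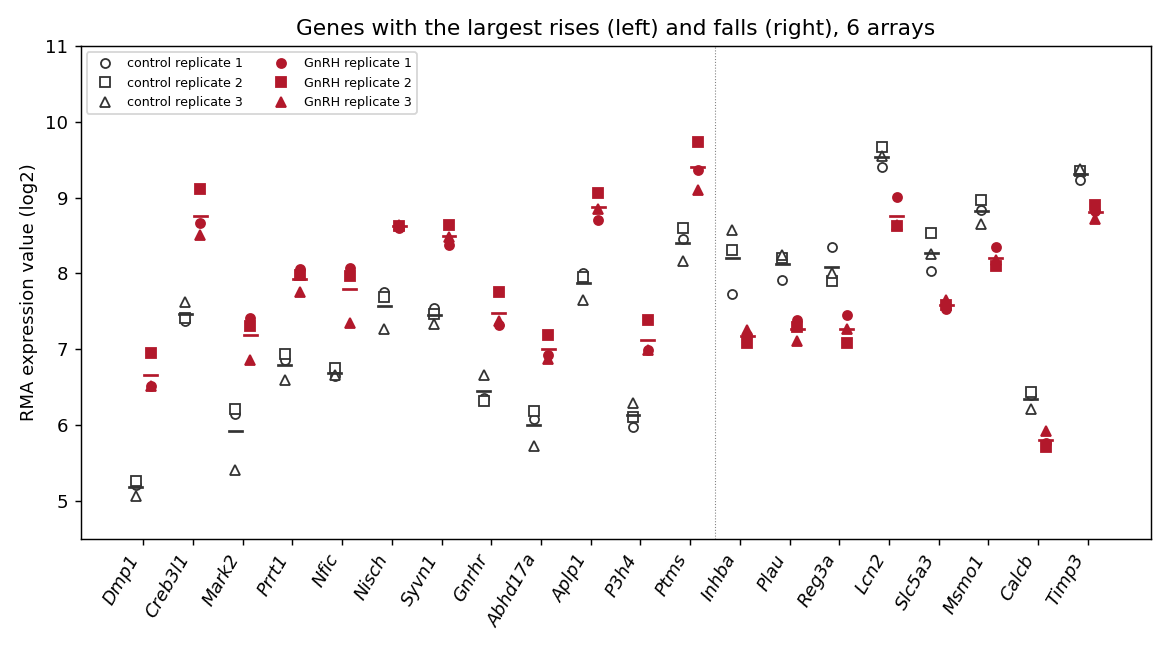
RMA expression values (log2) of the 12 genes with the largest rises and the 8 that fell, for each of the 6 arrays. Open black symbols are controls, filled red symbols GnRH samples, and short lines the group means; in every gene shown the 3 GnRH values lie on 1 side of the 3 control values, with Dmp1 between 5.07 and 5.26 in controls and between 6.52 and 6.94 with GnRH.

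Among 5 genes named in advance, the receptor changed and the hormone subunits did not pass the test. Gnrhr had log2 values of 7.85, 7.78 and 8.16 in controls and 8.78, 9.45 and 8.94 with GnRH on the brighter of its probe sets, a rise of 1.12 ± 0.17 (SE) or 2.18-fold (limma adjusted p = 0.0215). It rose by 1.04 ± 0.14 on the other, with 6.35, 6.31 and 6.66 against 7.31, 7.76 and 7.37 (limma adjusted p = 0.0129). Lhb, the LH beta subunit, had 12.03, 12.09 and 12.63 against 12.38, 12.67 and 12.71, a difference of 0.34 ± 0.16 (limma adjusted p = 0.425). Cga, the alpha subunit shared by LH, FSH and thyrotropin, had 12.84, 12.93 and 13.17 against 13.02, 13.27 and 13.19, a difference of 0.18 ± 0.11 (limma adjusted p = 0.536). Fshb, the FSH beta subunit, had 10.16, 10.19 and 9.34 against 8.86, 9.77 and 10.15 (difference -0.30 ± 0.30) on the brighter of its probe sets, with -0.36 on the other, and limma adjusted p = 0.723 and 0.713. Egr1, the immediate early transcription factor that drives Lhb, had 10.58, 10.55 and 9.47 against 10.36, 10.13 and 10.48, a difference of 0.12 ± 0.25 (limma adjusted p = 0.877). Without control 3, Lhb passed the test at 0.53 (limma adjusted p = 0.0192; 0.0192 to 0.991 over all alternatives) and Egr1 turned to -0.25 without passing. Lhb also passed at 0.44 with array weights, which gave control 3 the lowest weight (limma adjusted p = 0.0339). Against control 3 almost alone, with the Xist covariate, the difference was -0.0097 for Lhb and 0.79 for Egr1, whose control 3 value lay below all other arrays. Fshb turned with the array left out, to 0.065 and 0.064 without GnRH 1, with -0.58 and -0.70 without control 3, in no case past the threshold. The brighter Gnrhr probe set lost its call without control 1 (limma adjusted p = 0.0789), control 2 (0.0940), GnRH 2 (0.0658) or GnRH 3 (0.0545), and the other without control 2 (0.0649) or GnRH 2 (0.0613).

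In all, 144 of 31042 probe sets passed the threshold, 131 higher and 13 lower with GnRH, by limma with Benjamini-Hochberg adjustment. They stood for 100 different named genes that rose and 8 that fell, with 102 and 10 probe sets changed at least 1.5-fold and 14 and 2 at least 2-fold. The groups did not overlap in any of the 144, against 16.7% of all probe sets and 10% expected by chance. At an unadjusted p under 0.05 the direction was more even, with 2050 probe sets higher and 1758 lower. Control 3 was nearer to the GnRH mean than both other controls in 42 of the 144. Array weights gave control 3 the lowest weight, 0.298, and among controls rested mainly on control 2 (2.72, against 0.749 for control 1). They thus mostly set controls with low Xist against the GnRH arrays. The count of probe sets past the threshold was 69 without control 1, 28 without control 2 and 2309 without control 3 (1536 higher, 773 lower). It was 51 without GnRH 1, 20 without GnRH 2 and 65 without GnRH 3. With array weights it was 3020 (1763 higher, 1257 lower). With the Xist covariate, resting on control 3, it was 378 (311 higher, 67 lower), of which 103 were among the 144. Of the 26 named probe sets past the threshold, Dmp1, Creb3l1, Prrt1 and Syvn1 passed whichever array was left out, while 13 lost the call without control 1, 19 without control 2, 0 without control 3, 14 without GnRH 1, 22 without GnRH 2 and 14 without GnRH 3. Among 11 alternatives that kept the 6 arrays, Calcb, Nr5a1, Slc5a3 and Timp3 passed in 5, Chgb and Ptprn in 6, Msmo1 in 7, Drd2 and Reg3a in 8, Bhlhe41, Inhba and Ptms in 9, and Mark2, Nfic and the brighter Gnrhr probe set in 10. These 11 include the Xist fit, the only 1 of them that the brighter Gnrhr probe set did not pass.

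Gonadotrope hormone and identity genes lay above the other genes. Of 23 measured, Dmp1, Gnrhr and Nr5a1 rose, Inhba fell and 19 did not pass the test, with 5 rising and 1 falling when adjusted over the list alone. Nr5a1, the gonadotrope transcription factor SF-1, rose by 0.54 ± 0.10 (limma adjusted p = 0.0471). The mean shift of the list relative to all genes was 0.15 (camera, Benjamini-Hochberg adjusted p = 0.0216; adjusted p = 0.368 with an estimated correlation), and without control 3 it missed the threshold (camera adjusted p = 0.0928). Without dim probe sets, a step that left out Dmp1, the shift was 0.056 (camera adjusted p = 0.393; 0.0116 to 0.393 over all alternatives). The list also missed the threshold with array weights (camera adjusted p = 0.0578) and with the Xist covariate (0.0687). Without 1 array Nr5a1 passed only where that array was control 3, and it lost its call with median centring, quantile normalization, cyclic loess, either covariate and gene means (limma adjusted p from 0.0532 to 0.145).

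Genes of the secretory granule, the store from which pituitary hormones are released, showed the list shift with the smallest p-value. Chgb, the granule protein chromogranin B, rose by 0.59 ± 0.10 (limma adjusted p = 0.0449) and Ptprn, a granule membrane protein, by 0.66 ± 0.12 (limma adjusted p = 0.0484). The other 29 of 31 members did not pass, among them Pam (0.45) and Pcsk1n (1.39), whose 3 GnRH values of 9.06, 9.96 and 8.14 were spread widely above the controls. Adjusted over the list alone, 10 rose and 0 fell. The list lay 0.19 above all genes (camera adjusted p = 0.000333; adjusted p = 0.368 with an estimated correlation) and kept its call in each of the 6 fits without 1 array. Control 3 was lower than controls 1 and 2 in this list, by a median of -0.10, which lay at percentile 0.02 of random lists matched on expression. Genes of the random lists were drawn independently, here and below. Such percentiles therefore ignore correlation within a list and can overstate how unusual it is. Both single-gene calls were less stable, since without 1 array each passed only where that array was control 3. With 6 arrays Ptprn lost its call with quantile normalization, cyclic loess, an intensity trend, the replicate block and gene means (limma adjusted p from 0.0527 to 0.221). Chgb lost its call with median centring, cyclic loess, an intensity trend and either covariate (limma adjusted p from 0.0583 to 0.216).

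Immediate early transcription factors, which respond first to many stimuli, shifted upward as a list although 0 of 38 members passed over all probe sets. The members with the smallest p-values were Klf4 (0.55, limma adjusted p = 0.0534), Cebpb (1.34, limma adjusted p = 0.0705), Jund (1.08, limma adjusted p = 0.0835) and Klf9 (0.44, limma adjusted p = 0.133), and 8 rose and 0 fell when adjusted over the list alone. The mean shift was 0.17 (camera adjusted p = 0.0250; adjusted p = 0.589 with an estimated correlation). Control 3 was lower than controls 1 and 2 here by a median of -0.24, below all 10000 matched random lists. The call was lost without control 3 (camera adjusted p = 0.664, shift 0.075) and without GnRH 1 (0.0624). With all 6 arrays kept it was also lost with quantile normalization (camera adjusted p = 0.259), cyclic loess (0.326), dim probe sets left out (0.163), array weights (shift 0.089, 0.520) or the mean of all probe sets of a gene (0.0724).

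Steroid and nuclear receptors were shifted upward by 0.14 (camera adjusted p = 0.0216; adjusted p = 0.506 with an estimated correlation). Nr5a1 rose and 29 of 30 members did not pass. Adjusted over the list alone 6 rose and 0 fell. Ppard, a fatty acid sensor, had a log2 fold change of 0.59, the orphan receptor Nr4a1 0.67 and the progesterone receptor Pgr 0.68, with limma adjusted p-values of 0.0613, 0.207 and 0.229. The call was lost without control 3 (camera adjusted p = 0.111), without GnRH 2 (0.114) and with the mean of all probe sets of a gene (0.0651).

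Unfolded protein response genes, which help proteins fold in the endoplasmic reticulum, lay 0.12 above all genes (camera adjusted p = 0.0216; adjusted p = 0.741 with an estimated correlation). Syvn1 was the sole member of 30 that rose, also when adjusted over the list alone, and none fell. Hyou1 (0.48) and Xbp1 (0.39) lay higher and Ddit3 (-0.38) lower without passing. Ribosomal protein genes, kept as a comparison list, were shifted by 0.11 (camera adjusted p = 0.0147; adjusted p = 0.791 with an estimated correlation), with 26 of 28 log2 fold changes above 0 and 0 members past the threshold either way, such as Rpl30 (0.24), Rps24 (0.25), Rpl24 (0.25) and Rps13 (-0.19). In both lists control 3 was higher than controls 1 and 2, by medians of 0.31 and 0.39, at percentiles 98.8 and 99.8 of matched random lists. The unfolded protein response call was lost without control 1 (shift 0.062, camera adjusted p = 0.390), control 2 (0.110) or GnRH 2 (0.0546), and without control 3 the shift was 0.22 (camera adjusted p = 0.000246). It was also lost with quantile normalization (shift 0.069, camera adjusted p = 0.178), cyclic loess (shift 0.060, 0.326), dim probe sets left out (0.151) or gene means (0.0622). The shift turned to -0.0028 with the range of each array as a covariate (camera adjusted p = 0.718). That covariate was also chosen after the data were seen and divided the arrays much as Xist did. With the Xist covariate, against control 3 almost alone, the shift was -0.047. The ribosomal call was lost without control 1 (shift 0.046, camera adjusted p = 0.265) or control 2 (shift 0.061, 0.132), and without control 3 the shift was 0.22 (camera adjusted p = 1.83e-07). The ribosomal shift was 0.027 with cyclic loess (camera adjusted p = 0.326) and -0.037 with the range covariate (0.364), and lay at -0.097 with the Xist covariate (0.0171), where it rests on control 3.

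Genes of inflammation, cholesterol synthesis and secreted peptides were shifted downward. Among 37 cytokine, chemokine and NF-kappaB genes Lcn2 fell and 36 did not pass, with 1 rising and 4 falling when adjusted over the list alone. Ccl2, a monocyte-attracting chemokine, had -0.74, Ptgs2, the inducible cyclooxygenase, -0.55 and Nfkb2 0.47. The list lay at -0.15 relative to all genes (camera adjusted p = 0.0196; adjusted p = 0.480 with an estimated correlation), and at -0.12 without control 3, where the call was lost (camera adjusted p = 0.149). Of 24 cholesterol synthesis genes Msmo1 fell by 0.61 ± 0.11 and 23 did not pass, including Insig1 (-0.59), Cyp51 (-0.36) and Fasn (0.25), with 0 rising and 2 falling over the list alone. This list shifted by -0.12 (camera adjusted p = 0.0202; adjusted p = 0.589 with an estimated correlation). Control 3 was lower there than the other controls by a median of -0.16, and the call was lost without control 1 (camera adjusted p = 0.0559) or control 2 (0.10), with the range covariate (shift -0.056, 0.370) and with the Xist covariate (shift -0.025, 0.711). None of 36 neuropeptides and secreted growth factors passed. Penk, the enkephalin precursor, had -1.16 (limma adjusted p = 0.0554), Hbegf -0.72, Stc1 -0.37 and Vgf 1.26, and over the list alone 1 rose and 2 fell. Their shift was -0.11 (camera adjusted p = 0.0250; adjusted p = 0.589 with an estimated correlation). Control 3 was lower there by a median of -0.12, and the call was lost without control 1 (camera adjusted p = 0.0664), control 2 (0.110) or GnRH 3 (0.0585), with quantile normalization (0.0573) or gene means (0.0714), and with the range covariate (shift -0.051, 0.415) or the Xist covariate (shift -0.031, 0.908).

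Markers of other pituitary cells moved in both directions. Lactotrope markers, of the prolactin cells, were shifted by 0.24 (camera adjusted p = 0.0288; adjusted p = 0.480 with an estimated correlation). Drd2, the dopamine receptor of these cells, rose by 0.56 ± 0.10 (limma adjusted p = 0.0399). The other 9 of 10 did not pass, among them Prl itself (0.24), Pou1f1 (0.58) and Calb1 (-0.34), with 2 rising and 1 falling when adjusted over the list alone. Corticotrope and melanotrope markers were shifted by -0.35 (camera adjusted p = 0.0196; adjusted p = 0.589 with an estimated correlation) with 0 of 7 past the threshold and 1 falling over the list alone. Gpc3 had -0.65, Avpr1b -0.25, Pcsk2 -0.57 and Pomc, the corticotropin precursor, -0.82. Folliculostellate and stem-like cell markers, of the supporting cells, were shifted by -0.27 (camera adjusted p = 0.0147; adjusted p = 0.368 with an estimated correlation), with 0 of 17 past the threshold and 2 falling over the list alone. Gfap, a glial filament protein, had the largest difference of this list at -1.97 ± 0.42 but did not pass (limma adjusted p = 0.0835), with 7.92, 8.97 and 8.94 in controls against 7.69, 6.47 and 5.76. Cdh1 had -0.37, Clu -0.27 and Anxa1 -0.48. The folliculostellate call held in each of the 6 fits without 1 array, and in this list control 3 was lower than controls 1 and 2 by a median of -0.15. The lactotrope call was lost without control 1 (camera adjusted p = 0.0664), control 2 (0.0598) or GnRH 2 (shift 0.13, 0.114), and the corticotrope and melanotrope call without control 1 (0.0594) or GnRH 3 (shift -0.20, 0.0563). The lactotrope call was also lost with an intensity trend in the variances (camera adjusted p = 0.0536) and with gene means (0.0807). With the range and the Xist covariate, the camera adjusted p-values were 0.123 and 0.283 for lactotropes (shifts 0.12 and 0.055), 0.316 and 0.324 for corticotropes and melanotropes (-0.11 and -0.14) and 0.0845 and 0.0988 for folliculostellate cells (-0.26 and -0.27), and Drd2 lost its call with quantile normalization (limma adjusted p = 0.0982), cyclic loess (0.0982) or the Xist covariate (0.0524), and in each fit without 1 array other than control 3.

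The remaining cell type lists did not pass, and none of their members passed over all probe sets. Somatotrope markers lay at -0.025 relative to all genes (camera adjusted p = 0.786), with Gh1, the growth hormone gene, at -0.080, Rbp4 at -0.46, Dlk1 at -0.13 and Pou1f1, which alone of 9 rose over the list alone, at 0.58. Thyrotrope markers lay at 0.13 (camera adjusted p = 0.226), with Tshb at -0.48, Thrb at 0.52 and Trhr at 0.38, and Pou1f1 alone of 7 rising over the list alone. Fibroblast and pericyte markers had 5 of 20 rising and 5 falling when adjusted over the list alone, such as Igfbp5 (0.47), the collagens Col1a2 (0.61) and Col4a1 (0.50) against the proteoglycan Dcn (-0.63). The mean relative to all genes was -0.0026, the median 0.072 and the camera direction up (adjusted p = 0.790), and control 3 was lower than the other controls by a median of -0.29. Endothelial markers lay at 0.025 (camera adjusted p = 0.622; Plvap 0.40, Cldn5 -0.25, Eng 0.17, Tie1 0.12), macrophage and leukocyte markers at -0.038 (adjusted p = 0.551; Csf1r -0.21, Cd163 -0.18, Cd68 -0.15, Aif1 -0.16) and red blood cell markers at -0.075 (adjusted p = 0.772; Ahsp -0.29, Hbb -0.12, Alas2 -0.091, Slc4a1 0.076), with 0 members of these 3 lists changed over the list alone. The red blood cell list passed without GnRH 2 (camera adjusted p = 0.0493; 0.0493 to 0.977 over all alternatives). Posterior lobe and glial markers lay at -0.17 (camera adjusted p = 0.622), with Gfap falling and Nefl (0.45) rising over the list alone, Avp at -0.57 and Oxt at -0.43.

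Signalling and housekeeping lists mostly did not pass. Of 38 GnRH receptor signalling components, 0 changed over all probe sets or over the list alone. Gnas had 0.37, Src 0.35, Prkcd -0.25 and Mapk14 0.22, the mean relative to all genes was 0.012, the median -0.013 and the camera direction up (adjusted p = 0.786). MAP kinase and G protein feedback regulators had 0 of 33 past the threshold over all probe sets and 6 rising and 2 falling when adjusted over the list alone, with Rgs4 at 0.55 (limma adjusted p = 0.0576), Sik1 at 0.60, Errfi1 at -0.47 and Gem at -0.35, and a list shift of 0.055 (camera adjusted p = 0.355). In the activin, inhibin and BMP pathway Inhba fell and 37 of 38 did not pass, with Tgfb1 (0.37) also rising and Inhba falling over the list alone, Smad4 at 0.23 and Id4 at 0.19. The mean was -0.019, the median 0.016 and the camera direction up (adjusted p = 0.786). Bhlhe41, a transcriptional repressor of the clock, rose by 0.77 ± 0.12 (limma adjusted p = 0.0314) as the 1 changed member of 19 circadian clock genes, also over the list alone, with Per1 at 0.25, Cry1 at 0.26 and Nr1d2 at 0.44 (list shift 0.057, camera adjusted p = 0.551).

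Actin cytoskeleton and SRF target genes lay at -0.031 (camera adjusted p = 0.622), with 0 of 30 past the threshold and 3 rising and 1 falling over the list alone. Rhob had 0.83 (limma adjusted p = 0.0655), Myl9 0.45, Zyx 0.35 and Fhl2 -0.42. None of 40 cell cycle genes passed, and Ccnd3 (0.43) rose over the list alone, with Tk1 at -0.29, Ccne2 at -0.24 and Ccnd2 at -0.27. The mean was -0.0065, the median 0.017 and the camera direction up (adjusted p = 0.786). Glycolysis and hypoxia genes had 0 of 31 past the threshold and 2 rising and 1 falling over the list alone, with Ndrg1 at -0.50 (limma adjusted p = 0.0546), Pfkl at 0.38, Epas1 at 0.35 and Slc2a1 at -0.28. That list lay at 0.021 (camera adjusted p = 0.786), but passed upward at 0.15 without control 3 (camera adjusted p = 0.00622) and downward at -0.15 with the range of each array as a covariate, an alternative chosen after the data were seen (camera adjusted p = 0.000973), and at -0.21 with the Xist covariate (camera adjusted p = 2.21e-06), which rests on control 3. Its camera adjusted p ran from 2.21e-06 to 0.938 over all alternatives. Control 3 was higher than controls 1 and 2 there by a median of 0.37. Heat shock and oxidative stress genes lay at -0.12 (camera adjusted p = 0.0518), with 0 of 26 changed over all probe sets or over the list alone, Hmox1 at -0.55, Srxn1 at -0.46, Txnrd1 at -0.36 and Mt2A at -0.26, and control 3 differed from controls 1 and 2 by a median of 0.014, at percentile 0.44 of matched random lists. That list passed without control 1 (camera adjusted p = 0.00984), control 3 (0.0218) or GnRH 3 (0.0144), and with 6 arrays also with median centring (0.0407), quantile normalization (shift -0.16, 0.0290), cyclic loess (shift -0.18, 0.0144), dim probe sets left out (0.0189) or array weights (shift -0.22, 0.00725), with 0.00725 to 0.721 over all alternatives.

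Across the 27 lists, 12 passed camera's threshold, 7 upward and 5 downward, and 11 of 614 measured list genes passed limma's threshold over all probe sets, 8 higher and 3 lower. With an estimated correlation camera called 0 of the 27 lists and fry's directional test called 0, with 3 and 4 lists at an unadjusted p under 0.05. Fry's mixed test, which asks whether members changed in either direction, had 9 lists at an adjusted p under 0.05 in limma.

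**Figure D3:**
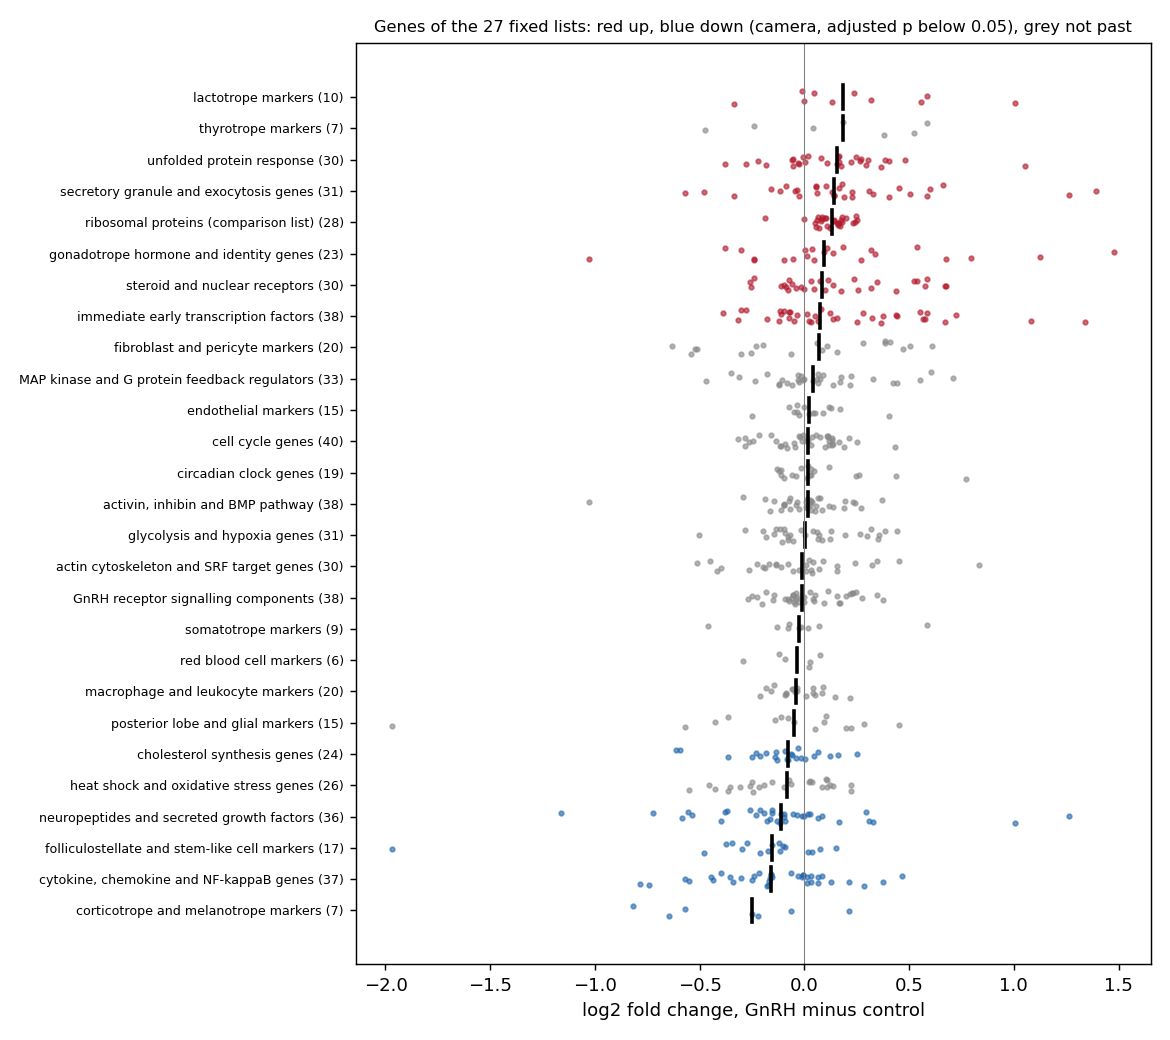
Log2 fold change (GnRH minus control) of every measured gene in the 27 lists, with the number of measured genes in brackets and a black bar at each list's median. Red lists shifted up and blue lists down by camera at an adjusted p under 0.05, and grey lists did not pass; 7 lists are red and 5 blue, and none passes with an estimated correlation.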

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

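The tests with the range or the Xist level of each array as a covariate were chosen after the data were seen, and the others before; the Xist fit set GnRH against control 3 almost alone (0.942 of the weight of the controls) and shows nothing on stability. The range covariate divided the arrays much as Xist did, so these 2 fits are not separate checks. Among controls, array weights rested mainly on control 2 (2.72, against 0.749 for control 1 and 0.298 for control 3). None of the 26 named probe sets past the threshold turned direction under any alternative. That says little, since their groups did not overlap, so leaving out or weighting arrays could not turn them. Of these 26, 11 passed in all alternatives that kept the 6 arrays and tested them, the Xist fit included. Dmp1, as a dim probe set, was left out of the fit without dim ones. Of the 123 named probe sets, 12 turned somewhere. Of the 12 lists called, 2 turned (the unfolded protein response and ribosomal proteins, with either covariate), 2 passed in all 6 fits without 1 array and 0 passed in all other alternatives, since an estimated correlation and fry each called 0. Camera on the mean of all probe sets of a gene called 7 lists, and each covariate 6. Against 144 changed probe sets (131 higher, 13 lower) and 11 list members, quantile normalization gave 90 (82 and 8) and 7, cyclic loess 93 (85 and 8) and 6, array weights 3020 (1763 and 1257) and 117, the range covariate 317 (274 and 43) and 27, and the Xist covariate 378 (311 and 67) and 37. Centring each array on its median left 7 lower, and the replicate block 20 lower with 22 members. The replicate numbers did not clearly pair the arrays. Deviations from the group means had correlations of -0.049 to 0.159 between arrays of the same number. Of the 6 arrays, 3 correlated best in this way with their own number in the other group. An adjusted p under 0.10 gave 341 (295 and 46), because more pass a wider threshold, and 1 probe set per gene 89 (81 and 8), with fewer tested. Of the 144, quantile normalization shared 86, cyclic loess 87, array weights 144, the block 129, the range covariate 113 and the Xist covariate 103. Without 1 array the counts ran from 20 to 2309 changed, 20 to 1536 higher, 0 to 773 lower, 2 to 101 list members and 7 to 11 lists; the lowest count of changed probe sets was without GnRH 2 and the highest without control 3. Turned list shifts were -0.0065 for GnRH receptor signalling and -0.023 for glycolysis with quantile normalization; -0.0044, -0.034 and, for cell cycle genes, 0.0015 with cyclic loess; -0.00072 for glycolysis without dim probe sets; and -0.011 for GnRH receptor signalling with gene means. With the range covariate they were -0.0028 for the unfolded protein response, -0.15 for glycolysis, past the threshold downward, 0.0092 for the cell cycle, -0.037 for ribosomal proteins, 0.036 for somatotropes, 0.12 for fibroblasts and 0.11 for red blood cells; with the Xist covariate, in the same order, -0.047, -0.21 and past the threshold, 0.014, -0.097 and past the threshold, 0.065, 0.14 and 0.12. Turned genes were Egr1 with array weights (-0.15) and, with the range covariate, Alas2 (0.042), Dlk1 (0.011), Hbb (0.47) and Tshb (0.036), and with the Xist covariate Dlk1 (0.16), Fshb (0.21 and 0.25), Hbb (0.60), Lhb (-0.0097), Rpl24 (-0.055), Rps24 (-0.055), Trhr (-0.029) and Tshb (0.18). Without 1 array, shifts ran from -0.065 to 0.022 for actin and SRF genes, -0.068 to 0.15 for glycolysis, -0.018 to 0.00084 for the cell cycle, -0.073 to 0.0027 for somatotropes, -0.013 to 0.053 for endothelium, -0.082 to 0.058 for fibroblasts and -0.22 to 0.037 for red blood cells. Log2 fold changes ran from -0.22 to 0.049 for Alas2, -0.25 to 0.31 for Egr1, -0.58 to 0.065 and -0.70 to 0.064 for Fshb, -0.52 to 0.13 for Hbb and -0.0012 to 0.13 for Slc4a1. Except for the wider threshold and the smaller number of tests, the cause was not tested. With no detection calls, signal over background could not be judged for a single probe set, so a small change in a dim one cannot be separated from background.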

Other observations

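The genes in this paragraph and the 2 gene groups of the next were chosen after their values were seen, as were the tests of a wrong label on control 3 and the 2 tests of the sex of the tissue. Among other risen genes, all with 3 GnRH values above 3 control values, were Mcl1, a survival factor of the BCL2 family (0.99 and 0.85 on its 2 probe sets), Cacna1g, a T-type calcium channel (0.97), Mknk2, a kinase below MAP kinases (0.93), Pim3, a survival kinase (0.90), and Bcl3, an NF-kappaB cofactor (0.85), whose brighter probe set gave 0.21 and did not pass. Dusp7, a MAP kinase phosphatase (0.73), Akt1 (0.69), the glutamate transporter Slc17a6 (0.68), Klf5 (0.67) and the somatostatin receptor Sstr3 (0.66) also rose, with limma adjusted p-values from 0.00586 for Bcl3, Pim3 and Cacna1g to 0.0411 for Akt1.

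Genes of the glycosylation and collagen-modifying machinery stood among the risen genes: Chpf (0.97), Mogs (0.95), Loxl1 (0.84), Mgat4b (0.81), Chst1 (0.59) and Maneal (0.51), beside P3h4. A hypothesis is that this machinery may have risen as a class. The 96 of 103 measured genes without a call lay above the others by 0.097, with 64 above 0 (camera p = 0.000905, adjusted p = 0.00181 over the 2 groups; p = 0.107 with an estimated correlation; p = 0.000103 without control 3). The same was asked of G protein subunits, where Gnb2 (0.73), Gna12 (0.57) and Gnaz (0.56) rose. The 27 genes of that group without a call had a mean shift of 0.011 (camera adjusted p = 0.856 by Benjamini-Hochberg over these 2 groups). A rise of that class may still hold and stays open.

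Control 3 lay apart from controls 1 and 2, and without it 2309 probe sets passed. A different range of intensities is argued against by the spread of its differences, 1.59 times that between controls 1 and 2 after cyclic loess and 1.65 before. A hypothesis is that controls 1 and 2 came from males and the other arrays from females: on a scale from 0 (controls 1 and 2) to 1 (GnRH mean) control 3 lay at 0.881 or more on every probe set of Xist and Eif2s3y, although 1 probe set of the Y-linked Uty ran against this, and with sex confounded in part with treatment it stays open how many of the 2309 it may account for. A GnRH-treated sample under a wrong label stays open, as the values pointed both ways. With control 3 beside controls 1 and 2, 144 probe sets passed, against 0 with any GnRH array in its place. So few arrangements cannot decide, since 1 of them must come first. Unadjusted counts did not set control 3 apart (3808 at p under 0.05 by limma, against 2059 to 4532). Gnrhr lay at 0.29 and 0.28 on the same scale. Where probe sets were chosen with neither control 3 nor 1 GnRH array, 10.4% to 16.0% lay below 0 in control 3. In the GnRH array left out, 0.693% to 1.37% did. The median positions of control 3 over those probe sets were 0.758, 0.864 and 0.748 without GnRH 1, 2 and 3. Those of the GnRH array left out were 0.722, 1.05 and 0.909. The median position of control 3 over the 2309 was 0.845, with Lhb at 1.08. The 2309 and the probe sets chosen without 1 GnRH array were all called between arrays of low and high Xist. Their median positions therefore cannot tell a wrong label from a difference of sex. A different tissue make-up may contribute and stays open, as 2 of 10 cell type lists (folliculostellate and fibroblast) lay outside the central 95% of 10000 random lists, as did 8 of 17 pathway lists. The random lists drew genes independently, so a list of correlated genes can lie outside more easily.

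Far more probe sets rose than fell, 131 against 13. Further normalization between arrays did not remove the excess, as the lowest share that rose over 3 other normalizations was 91.1%. These were run on values already processed with RMA. They therefore cannot tell whether that earlier step caused the excess, which stays open. The split was 1536 to 773 without control 3 and 1763 to 1257 with array weights. Base composition shared by neighbouring genes may contribute and stays open, since 387 uncalled neighbours of 100 risen genes had a mean log2 fold change of 0.053 against 0.011 in random draws (one-sided permutation p = 3e-05), far below the changes of the risen genes themselves, and GC content itself was not tested. Another sex in controls 1 and 2 as the whole cause stays open. With any of the 3 GnRH arrays in the place of control 3 beside them 0 probe sets passed, but so few arrangements cannot decide. Unadjusted counts did not set the real grouping apart. At p under 0.05 by limma they were 4532, 2729 and 2059 with GnRH 1, 2 and 3 in that place, against 3808 with control 3. A part of sex in single genes and an effect of GnRH, the biological difference in the design, stay open. The real split called 144 probe sets and the highest of the other 9 splits of the arrays 0, and 1 of the 10 splits gave as many, too few splits for a share under 0.05.

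For gene lists the real split called 12 and the highest other 9, and 1 of the 10 splits gave as many, which again are too few for a share under 0.05.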
